A study of Mus musculus with 2 samples.

How the data were processed

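The study measured where the transcription factor Nkx6.1 is bound to DNA in mouse pancreatic islets, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). One set of islets gave 1 Nkx6.1 ChIP library and 1 input library, input being sheared chromatin sequenced without an antibody step. The labels assign each library to its group by the antibody entry. No replicate exists for either group in the labels, so no value below carries an error between animals, and intervals cover counting error only, except where they are said to be over peaks or widened for the spread of peaks over windows.

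One peak list was analysed. Peaks were called with HOMER findPeaks in its factor style on the ChIP tags against the input tags, per the file headers, and the submitters' processing notes also name Bowtie and the mm9 genome build. Versions and the alignment settings are not given in the sources used here. Per the file headers, the caller was run at a false discovery rate of 0.001 with a ChIP fragment length of 80 bp, and it gave each peak a fixed size of 133 bp centred on the highest tag pile-up. Per the file headers, a peak had to reach 4-fold over input and 4-fold over the surrounding 10000 bp, each with a Poisson p-value of at most 0.0001, and at most 10 tags were considered per position.

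The deposited columns hold several units. The normalized tag signal is scaled by the authors to 10000000 tags. The ChIP tag signal used for the input comparison was deposited as values that step by 0.788. Dividing by that step gave whole tags, within 0.1 tag, for 100% of peaks. These tag numbers are larger than those behind the normalized column and the tags in peaks that the header states, so the columns do not count the same tags, and the width of each counting window is not given in the sources used here. If the step is the ratio of the library totals, the input library held about 1.60e+08 tags, against the 202780986 ChIP tags that the header states. The input tag signal was deposited as whole numbers of 22 or more, or as the single value 21.4. As no lower value occurs, 21.4 is read here as the minimum that the caller put in place of every lower input count. The fold over input is a deposited ratio of the ChIP to the input column, and recomputing it from those columns changed it by at most 0.221%. The peak score and the focus ratio, a fraction that describes how tags of each strand sit around the peak centre, are also as deposited by the authors. The deposited p-value column is a Poisson p that measures these 2 libraries, not islets in general, and it was written as 0 for 563 peaks.

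The deposited list pairs no peak with a gene. The gene table at hand uses another assembly (GRCm38), so peaks are given by their mm9 position, and no coordinate was converted. The planned comparisons that need mm9 genes or sequence (promoter share, the fixed gene lists, motif shares, and strength by distance to a transcription start) were not run. The naming rule, fixed before the data were examined, then gives the 10 highest scoring peaks and the 3 densest clusters by position. As 3 clusters tied at 6 peaks for the last place, all 3 are named, which widens the rule to 5 clusters and was decided after their values were seen.

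Peaks were counted per chromosome and divided by the distance between the first and last peak centre, since mm9 chromosome lengths were not used here. Densities carry exact Poisson intervals, and chromosomes were compared by chi-square. As peaks lie in groups, the chi-square was also divided by the variance-to-mean ratio of peak counts in autosomal windows of 1 Mb. The X to autosome ratio was tested with an exact two-sided binomial test, and its interval was also widened by that variance-to-mean ratio. Neighbours were counted by the distance between peak centres, with 10 kb as the main distance. The share was set against 1000 random placements of the peaks within the span of their chromosome, two-sided, for which the smallest p is 0.002. In 20 sets of uniformly simulated peaks this test called 0, and in 20 sets with planted pairs it called 20, each over 15237 peaks. Of 20 sets with regional differences in density and no planted pairs, uniform placement called 20 and placement within 250 kb called 0. The simulated regions were far wider than 250 kb, so false calls from density that varies over shorter distances were not checked. Shares carry exact Clopper-Pearson intervals and medians carry order-statistic intervals over peaks, both at 95%. Clustered and isolated peaks were compared with 100000 permutations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Stricter fold and p thresholds, the upper part of the list by score, other neighbour distances and placements within 250 kb and 50 kb of each peak were tried as alternatives. The upper part by score held the 7537 peaks with a score above 175.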

Results

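Nkx6.1 is a homeodomain transcription factor that insulin-producing beta cells of the islet depend on. Its binding sites were mapped in pancreatic islets of C57Bl/6 background, with 1 ChIP library of 202780986 tags and 1 input library. The list holds 15239 peaks of 133 bp each on 19 autosomes, chromosome X and the mitochondrial genome. No peak was listed on chromosome Y. Per the header, tags in peaks made up 0.827% of all ChIP tags. In the tag column used for the input comparison the median peak held 172 ChIP tags (interquartile range 134 to 242). In the normalized column, which counts tags differently, the median was 4.3 per 10000000 tags. As each group has 1 library, the differences described below have no replicate check.

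The first comparison asks where Nkx6.1 ChIP tags exceeded input. The strongest site in the nuclear genome lay on chromosome 6 at 21899984 to 21900116, with 3152 ChIP tags (95% Poisson interval 3043 to 3264) and 78 input tags, a deposited fold of 31.9 (exact conditional interval 25.4 to 40.4). The next by score was on chromosome 2 at 92929920 to 92930052, with 2268 ChIP tags over 31 input tags and a fold of 57.7 (40.5 to 85.1). A site on chromosome 7 at 86739937 to 86740069 followed with 2152 ChIP tags over 43 input tags, at 39.5-fold (29.2 to 54.7). It stood 149.98-fold above its surrounding 10000 bp, the highest local enrichment in the list. The site on chromosome 11 at 88029747 to 88029879 reached 57.1-fold (38.8 to 87.6), and the site on chromosome 5 at 4004993 to 4005125 reached 30.1-fold (22.7 to 40.7). The highest deposited fold over input in the list, 62.4 (41.0 to 99.7), was on chromosome 1 at 97213682 to 97213814. Peaks whose input stood at the minimum value may exceed it, as their deposited fold is a lower limit. The site on chromosome 4 at 140410567 to 140410699 had 59.5-fold (39.5 to 94.2). On chromosome 16 at 75831954 to 75832086 the deposited fold was 58.4, computed against the minimum input value. The intervals of the sites on chromosomes 1, 2, 4, 7 and 11 overlapped, so their order by fold was not resolved at this depth. Those of the sites on chromosomes 5 and 6 ended barely below the interval of the site on chromosome 1 (40.7 and 40.4 against 41.0). As that site was singled out for the highest fold in the list, this gap is not a test of their order.

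The 2 highest scores in the whole list belonged to the mitochondrial genome, which is present in many copies per cell. The peak at 15401 to 15533 had 25743 ChIP tags over 4023 input tags, a fold of 5.04 (4.88 to 5.22). The peak at 16006 to 16138 had 18652 ChIP tags over 1449 input tags, a fold of 10.2 (9.62 to 10.7). Both carried far more input tags than any nuclear peak, the highest of which had 285.

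Across the list the median fold over input was 5.63 (5.59 to 5.67 over peaks), and the median fold over the local region was 9.94 (9.86 to 10.01). Of the 15239 peaks, 9825 reached 5-fold over input, 3668 reached 8-fold, 353 reached 20-fold and 11 reached 50-fold. Input stood at the minimum value of 21.4 tags for 10225 peaks, or 67.1% (66.3 to 67.8). For these peaks the fold over the input tags present is at or above the deposited one. The list begins at 109 ChIP tags, the number that makes 4-fold over that minimum. The other 5014 peaks had a median of 27 input tags and a median fold of 5.52 (5.48 to 5.59). Per the authors' deposited header, 885361 putative peaks were found, of which 869984 were removed by the input filter, 133 by the local filter and 5 as too clonal. The input filter thus removed 98.3% of them. No site under 109 ChIP tags can pass this filter whatever its input, so removal need not mean high input.

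**Figure D1:**
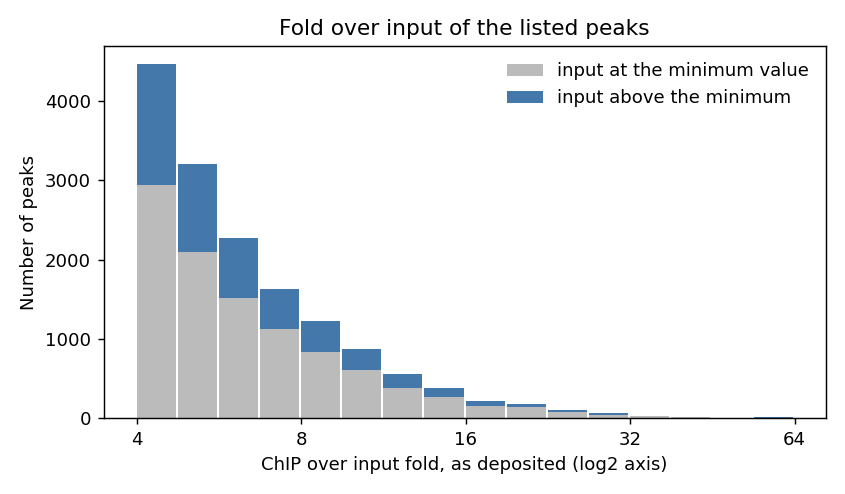
Number of listed peaks (y axis) by deposited ChIP over input fold (x axis, log2 scale), with grey for the 10225 peaks whose input stood at the minimum value and blue for the 5014 with more input. Counts are highest just above the 4-fold limit of the caller, while 9825 peaks lie at 5-fold or more and 3668 at 8-fold or more.

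The second comparison asks how the sites were spread over the chromosomes. Autosomes held 6.35 ± 0.796 peaks per Mb (SD, n = 19 autosomes). Chromosome 11 was densest with 8.11 peaks per Mb (7.60 to 8.63) and 959 peaks, followed by chromosome 19 with 7.96 (7.25 to 8.72). Chromosome 3, with 5.26 (4.90 to 5.63), and chromosome 12, with 5.29 (4.88 to 5.72), were the sparsest autosomes. Chromosome X held 192 peaks at 1.20 per Mb (1.04 to 1.39), which is 0.192 of the autosomal density (0.165 to 0.221; exact two-sided binomial p = 1.1e-206). With counting error widened for the uneven spread of peaks over 1 Mb windows, the interval was 0.143 to 0.257. X peaks also held fewer tags, with a median of 146.5 (139 to 157) against 172 (171 to 174) on autosomes, and 8.85% of them (5.24 to 13.8) had input above the minimum. Counts differed over the 20 chromosomes (chi-square 861 on 19 degrees of freedom, p = 2.8e-170) and over the autosomes alone (204 on 18, p = 1.7e-33). Divided by the variance-to-mean ratio of 4.24 found in 1 Mb windows, the chi-square became 203 (chi-square p = 9.0e-33) and 48.1 (chi-square p = 0.000147), respectively. That ratio does not allow for density shared between neighbouring windows, so these p-values and the widened interval may still be too narrow. These tests treat 2 libraries and do not measure variation between animals.

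**Figure D2:**
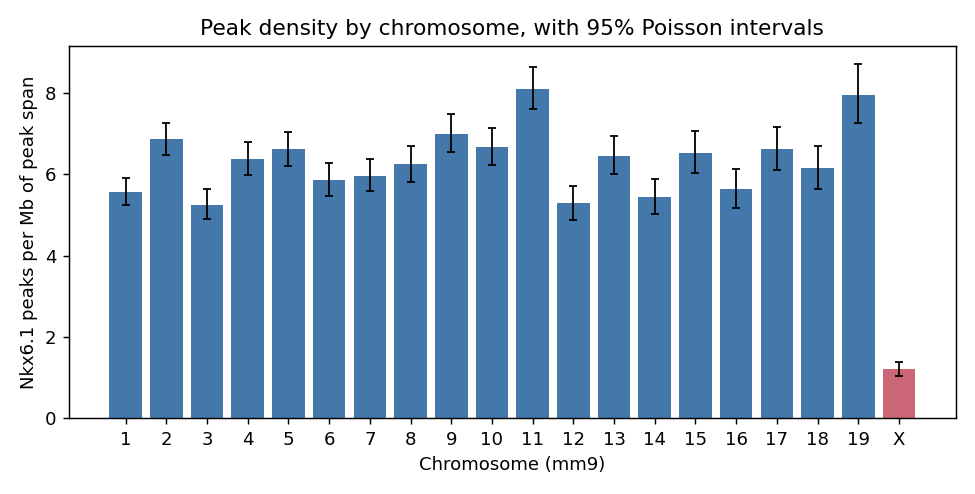
Nkx6.1 peaks per Mb (y axis) for each mm9 chromosome (x axis), as counts over the distance between its first and last peak, with 95% Poisson intervals as error bars. The 19 autosomes (blue) lie between 5.26 and 8.11 peaks per Mb and chromosome X (red) at 1.20.

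The third comparison asks whether sites lay in groups. Of 15237 nuclear peaks, 4277 had another peak centre within 10 kb, or 28.1%, against 11.8% ± 0.360 (SD over 1000 placements) when peaks were placed at random over their chromosome (highest placement 13.0%, two-sided permutation p = 0.002, the smallest these placements can give). The share was 2.38 times that of these uniform placements, which do not keep regional differences in density. Linking peaks at most 10 kb apart gave 1919 clusters with 4277 peaks, and 348 of these clusters had 3 or more. The densest cluster lay on chromosome 9 from 61213998 to 61227150, with 7 peaks in 13.2 kb whose folds over input ran from 6.24 to 29.3. A cluster of 7 peaks in 20.9 kb lay on chromosome 10 from 59484431 to 59505369, with folds from 6.29 to 24.2. Clusters of 6 peaks lay on chromosome 3 from 31182241 to 31209289, on chromosome 19 from 28731403 to 28759260 and on chromosome 8 from 123011768 to 123045216. Placing each peak within 250 kb of its own position keeps density over much wider regions and flattens it over shorter distances. Such placements gave 18.3% (highest 19.5%), and placing peaks within 50 kb gave 22.2% (highest 23.5%). The observed share was 1.53 and 1.26 times these, respectively (two-sided permutation p = 0.002 for each, the smallest possible; both placements were chosen after the files were seen). The caller's rule of 4-fold over the local 10000 bp works against closely spaced peaks, and placements did not exclude unmappable sequence.

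**Figure D3:**
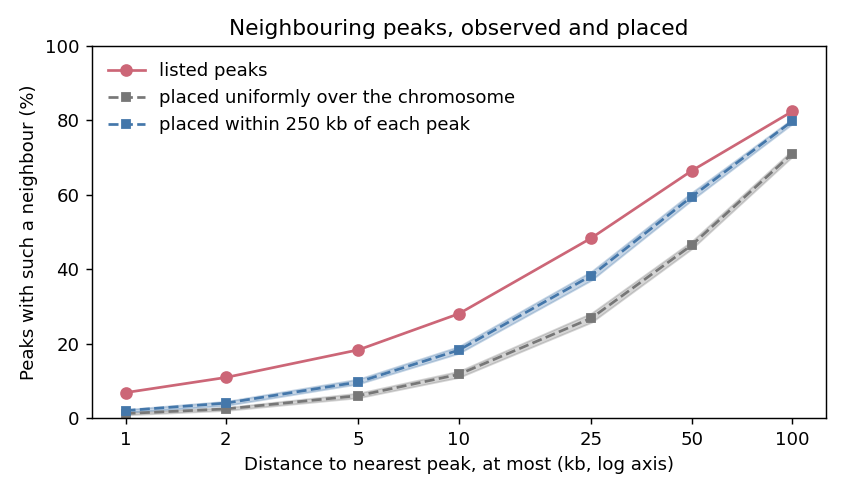
Percentage of nuclear peaks with another peak within a given distance (y axis) against that distance in kb (x axis, log scale), for the listed peaks (red), peaks placed uniformly (grey) and peaks placed within 250 kb of themselves (blue); lines are means and bands the range over 100 placements. The listed peaks lie above both at each distance, with 6.88% against 1.27% and 2.05% at 1 kb and 82.4% against 71.1% and 79.8% at 100 kb.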

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

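The number of peaks and their median fold depended on the threshold, while the X to autosome ratio and the clustering kept their direction and their side of 0.05 under the alternatives that were run. The chi-square over 20 chromosomes, which has no direction, stayed past 0.05 in the upper part of the list by score (563) and at 8-fold or more (248), and the densities of the autosomes alone were not rerun. The X to autosome ratio and the settings that joined peaks, left out chromosome X, changed the placement or kept peaks by their input level were chosen after the files were seen. At 8-fold over input 3668 peaks were left, and 5014 had input above the minimum, while autosomes with X held 15237. A p under 1e-10 removed no peak, but it could not, as the largest deposited Poisson p over input was 3.1e-25. The median fold of 5.63 became 5.45 with 1 tag added to each side, 7.91 in the upper part of the list by score, and 5.52 in peaks with input above the minimum. The rise in the upper part is partly built in, as score tracks ChIP tags, from which the fold is computed. The share of peaks with a neighbour within 10 kb was 18.0% in the upper part by score and 28.3% without chromosome X. It was 22.9% with peaks under 1 kb apart joined and 14.6% in peaks with input above the minimum. Each lay above its highest uniform placement. Within 5 kb the share was 18.4% against 6.09% placed uniformly, and within 25 kb 48.4% against 26.9%. Uniform placement also called 20 of 20 simulated sets with regional density and no planted pairs. These settings therefore do not separate grouping from regional density. The X to autosome ratio of 0.192 was 0.131 in the upper part by score, 0.153 at 8-fold or more and 0.262 in peaks with input at the minimum. It was not computed for the 5014 peaks with input above the minimum, of which 17 lay on X. No paired analysis was possible because each group has 1 library. The alternatives planned for promoter share, gene lists, motif shares and strength by distance to a transcription start were not run, as no mm9 annotation or sequence was used here. With input at the minimum for 67.1% of peaks, the minimum that the caller put in limits the fold values, and sites under 109 ChIP tags cannot be in the list.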

Other observations

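The tests of peak strength and of chromosome X were chosen after the values they bear on were seen. Those of clustering were chosen after the list was seen but before their results. Listed peaks were unevenly spread at the scale of 1 Mb. Neither windows nor gaps were corrected for unmappable sequence or input coverage, so an empty stretch need not lack binding. The autosomal windows held a median of 5 peaks, while 257 of 2414 held none and 40 held 20 or more. The window with most peaks was on chromosome 18 from 55000001 to 56000000, with 32 peaks and a highest score of 380. Windows of 28 peaks lay on chromosome 15 from 27000001 to 28000000 and on chromosome 17 from 56000001 to 57000000. The window on chromosome 3 from 51000001 to 52000000 held 26 peaks with a median fold of 7.62, and 11 of these reached 8-fold. The longest autosomal gap between 2 neighbouring peaks, 7.72 Mb, was on chromosome 7 between 38986133 and 46704794, and chromosome X had a gap of 12.99 Mb between 20527995 and 33516655.

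Peaks with a neighbour within 10 kb were slightly stronger than isolated ones, with a median of 178 against 170 ChIP tags (0.07 higher on the log2 scale, 4277 against 10960 peaks, two-sided permutation p = 2.0e-05). This test treated each peak as independent, although the 4277 peaks lay in 1919 clusters. Its p makes no allowance for strength shared within a cluster or for the chromosome of each peak, and is too small to that extent. The share with a neighbour within 10 kb was 23.4% in the weakest decile of peaks by ChIP tags and 30.3% in the strongest. The focus ratio was 0.759 in the weakest decile and 0.827 in the strongest. The local fold was 7.34 and 24.6, a rise that is partly built in, as this fold is itself ChIP signal over its surroundings. A peak on chromosome 2 from 5300311 to 5300443 stood apart with 1776 ChIP tags, 285 input tags, a focus ratio of 0.997 and a clonal fold of 1.55, where the median peak had 0.86.

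Chromosome X held 19.2% of the autosomal peak density (16.5 to 22.1), and a candidate explanation is that the islets carried 1 copy of X per cell, which would halve its tags against a fixed minimum of input. With tags and input halved, 31.7% of autosomal peaks (31.0 to 32.5) would still pass the 4-fold rule. Against the sparsest autosome, chromosome 3, the observed density was 22.9%, and its upper limit from counting error alone, 26.8%, met the value set to exclude 1 copy as the whole cause. That limit ignores the uneven spread of peaks over 1 Mb windows. Once widened for it, the upper limit was 25.7% against all autosomes but 31.68% against chromosome 3. The latter lies barely below the share of 31.74% that the rule names, and inside its interval of 31.0 to 32.5. Asking for a limit below that interval is stricter than the rule, and on that stricter reading the explanation stays open. Peaks on X had input above the minimum in 8.85% of cases, against 27.3% of autosomal peaks with the same ChIP tags, and the 4776 autosomal peaks that would pass after halving would then hold a median of 147.5 tags, against 146.5 on X; lower mappability of X would lower input as well, and fewer Nkx6.1 sites on X were not tested, as the labels give neither sex nor a second tissue.

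Peaks may lie together because some large regions bind more, or because the caller splits broad regions into peaks under 1 kb apart. Placements within 250 kb keep density over much wider regions and reached at most 19.5%, against 28.1% observed. After peaks under 1 kb apart were joined, 22.9% of 14702 sites still had a neighbour within 10 kb, above the highest placement within 250 kb (18.7%) and within 50 kb (21.8%). The excess was smaller than without joining, at 1.31 and 1.11 times the mean of these placements, respectively. Neither density over regions much wider than 250 kb nor splitting into pieces under 1 kb apart therefore accounts for the whole excess. As joining removes the closest pairs whatever their cause, the share that came from such splitting is not known. The placements flatten density that varies over shorter distances and left unmappable sequence in, so a part played by either is not excluded. Splitting of wider regions into pieces 1 to 10 kb apart, which joining would leave in place, and shared open chromatin were not tested and stay open.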
